A study of Homo sapiens with 6 samples.

How the data were processed

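The series holds 6 RNA-seq libraries of HCT116 cells in 3 groups of 2 (WT, KO1, KO2). Per the labels' protocols, poly(A) RNA was purified and libraries were made with a NEBNext Ultra RNA kit. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The deposited tables give read counts per gene symbol and library, which the authors made before normalization, per the file headers. The submitters' processing notes name STAR, HTSeq 0.6.0, DESeq2 and the build hg18, without saying which step each served. The tables also give a log2 fold change, a p-value and an adjusted p-value per gene from the authors' own comparison of each guide with WT, per the file headers. The authors' deposited normalized counts and FPKM, and the counts repeated in their filtered lists, 40 columns in all, were not used.

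The WT counts are identical in the 2 tables, so the tables were joined on gene symbol. They share 15284 genes. Another 264 genes are listed for KO1 only and 429 for KO2 only, and none of these has a read in WT. Counts were analysed as deposited. Column names give the group and a prefix (HCT or HCT116) but no replicate number, so the replicate numbers of the labels could not be assigned to columns. Chi-square per degree of freedom between the 2 libraries of a group was 142 in WT, 119 in KO1 and 91.5 in KO2, so the 2 libraries of a group were not copies of each other.

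Tests used edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr by group with a minimum count of 10, glmQLFit and glmQLFTest on all 6 libraries, and Benjamini-Hochberg adjustment at 0.05. This kept 12678 genes. Standard errors are the absolute log2 fold change divided by the square root of F. Where a group has few reads, they can understate counting error. CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. The design fixed before the data were examined has group means only and 3 residual degrees of freedom. After the data were seen the prefix was added as a block, which leaves 2. The prefix pairs libraries across groups in the data: deviations from the group means correlated across genes at 0.867 between WT and KO1, 0.815 between WT and KO2 and 0.783 between KO1 and KO2. With this replicate block 130 genes were called in KO1 against WT, 585 in KO2 against WT and 1220 in KO2 against KO1, against 0 in each without it. Because the labels do not explain the prefix, both fits are given.

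The 28 gene lists, with 947 entries, were fixed before the data were examined and cover the PI3K/Akt/mTOR pathway, related stress, growth and differentiation programmes, mucins, genes near MUC3A, and markers of leukocytes, fibroblasts and the HEK293T packaging cell line. Lists with at least 5 tested members (27) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with fry and an estimated correlation as alternatives. With an estimated correlation and with fry, 0 lists passed in each comparison and fit. With the block and an estimated correlation, camera gave 0 lists an unadjusted p under 0.05 in each comparison. Whether these alternatives can recover a shifted list from so few libraries was not tested, so a high p there may reflect low power. Fibroblast markers had 3 tested members and 0 of these changed with either guide by edgeR with the block (adjusted over the list alone, 2 rose in KO1). Of 6 HEK293T lineage genes 0 changed with either guide (adjusted over the list alone, 1 rose and 3 fell in KO2), and of 7 leukocyte genes 0 changed (1 rose in KO1 adjusted over the list alone).

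Named genes follow a rule fixed before the data were examined. It takes MUC3A. From each comparison with WT it takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and both knockout libraries on the same side of both WT libraries. From each list it takes up to 3 called members with the smallest p. It adds the 6 genes that rose and 6 that fell in both comparisons with the smallest p, and the 5 largest differences in each direction between the guides. Since the fixed design called 0 genes, the rule was applied to the fit with the block. Some genes the rule takes are not reported here. For genes with 0 reads in a group a fold is given as a bound against 3 counts over the group, and for 1 to 3 reads as a count ratio with a 95% exact (Clopper-Pearson) interval, covering counting error only. At depths of 13638724 to 17830282 counts, 3 counts correspond to 0.157 to 0.236 CPM in a single library.

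Guides were matched to GENCODE transcripts on GRCh38 with up to 3 mismatches and an NGG PAM. Since the counts were made on another build, the annotation served otherwise only for gene order, GC content and length, and all 12678 tested genes had values. Chromosome windows were medians of 31 neighbouring genes. The scripts were tested on simulated counts for 12678 genes in KO1 against WT with 200 changed genes. The counts were drawn from the fit with the block, so a prefix difference was built into them. Recovery with and without the block therefore does not tell which fit suits the real data. With the block edgeR recovered 85 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 10 false calls. Without it edgeR recovered 0 of 100 at each fold, limma-voom 0 and 0, and DESeq2 1 and 64. A list of 28 shifted genes was recovered by camera at the preset correlation, and a lowered window of 31 genes was found with 30 of its genes among 9584. Simulated genes were drawn independently of each other, so recovery of the list does not check the preset correlation for genes that vary together.

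Other choices tried were median-of-ratios size factors, library size only, no filter, a stricter filter (CPM of at least 1 in every library of a group), DESeq2 1.42.0, limma-voom, only the 4 libraries of the groups compared, the authors' kind of threshold, a log2 threshold of 1 with adjusted p, and leaving out each library in turn. All were repeated with the block, where a per-library loess correction for GC content and length, genes of either table with 0 where not listed, and the fit without the chromosome 16 window were added after seeing the data. No group has 3 libraries, so regroupings of samples were not run.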

Results

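RNA was measured by poly(A) RNA sequencing in HCT116 cells, a human colorectal carcinoma cell line, with and without CRISPR editing of MUC3A. MUC3A encodes a membrane-bound mucin of the intestinal epithelium. Cells were infected at a multiplicity of infection of 10 with lentiCRISPR v2 virus, which carries Cas9 and a guide RNA, and were selected with puromycin at 2 µg/mL for 72 h. The 6 libraries formed 3 groups of 2: control cells (WT), cells given the first MUC3A guide (KO1) and cells given the other guide (KO2). The labels call the controls both wild type and negative control, and the protocol describes a scrambled virus, so whether WT cells were infected was not settled here. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Total counts per library were 14325699 and 13638724 in WT, 14370065 and 13670401 in KO1, and 17830282 and 15277378 in KO2.

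Both guides match exon 2 of MUC3A, inside the coding sequence. By sequence match to GRCh38, the KO1 guide GAAGGCAAACTTGGACGTCG lies on chromosome 7 at 100952090 to 100952109, on the strand opposite to the transcript. The KO2 guide TTCTCCACACTCCAGAGACC lies at 100951917 to 100951936 on the transcript's own strand. The exon belongs to annotated MUC3A transcripts of 12 and 11 exons. Among annotated transcripts, the only other gene matched with up to 3 mismatches and a PAM was RTRAF, for the KO2 guide, with 3 mismatches. RTRAF did not change in KO2, at a log2 fold change of 0.09 ± 0.12 (SE, n = 2 libraries per group) and an adjusted p of 0.726 by edgeR.

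MUC3A transcript passed the threshold with neither guide. In the libraries whose names start with HCT, MUC3A stood at 52.7 CPM (counts scaled to library size) in WT, 52.9 in KO1 and 30.04 in KO2. In the libraries whose names start with HCT116 it stood at 25.1 in WT, 28.6 in KO1 and 24.6 in KO2. By edgeR's quasi-likelihood test the log2 fold change against WT was 0.07 ± 0.48 (SE, adjusted p = 0.99998) in KO1 and −0.51 ± 0.48 (SE, adjusted p = 0.99999) in KO2. With the set of libraries described next as a term it was 0.08 ± 0.18 (SE, edgeR adjusted p = 0.962) and −0.43 ± 0.19 (SE, adjusted p = 0.237). Insertions and deletions need not change the amount of a transcript, so gene-level counts do not check the knockout labels. Leaving out the HCT116 library of WT (−0.37) or the HCT library of KO1 (−0.44) turned the sign in KO1, as leaving out the HCT library of WT (0.12) did in KO2. With the set term, the fall in KO2 passed the threshold in edgeR without the HCT116 library of KO2 only (−0.77, adjusted p = 7.64e-05).

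The libraries split by name prefix more than by guide. Each group has 1 library named HCT and 1 named HCT116, called the HCT set and the HCT116 set here, and the labels do not say what the prefix marks. Libraries of the same set correlated across genes in log2 CPM at 0.962 to 0.986, and the 2 libraries of a group at 0.924 to 0.958. With group and set in 1 edgeR model, 8105 of 12678 tested genes differed between the sets, 4036 higher in HCT116 and 4069 higher in HCT. The biological coefficient of variation was 0.383 without the set in the model and 0.118 with it. In the design fixed before the data were examined, which has no set term, edgeR called 0 genes at an adjusted p of 0.05 in each of KO1 against WT, KO2 against WT, KO2 against KO1 and the mean of both guides against WT. At an unadjusted p of 0.05 it gave 173, 309, 513 and 134 genes. DESeq2 called 16, 42, 118 and 15 genes without the set term, and limma-voom 0 in each. The gene values that follow come from the edgeR fit with the set as a term, chosen after seeing the data, with log2 ratios within each set where they matter.

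KO1 was compared with WT to find the genes that change with the first guide. The gene that fell most in KO1 was DPYSL5, a cytoskeletal protein of the dihydropyrimidinase-like family, from 40.3 and 41.4 CPM in the WT libraries to 0.402 and 0 in KO1 (log2 fold change −7.52 ± 0.39, SE, n = 2 libraries per group, edgeR adjusted p = 7.96e-06). It had 6 reads in KO1 against 1145 in WT, so its SE understates counting error. Keratin 13 (KRT13) rose 18.6-fold (4.22 ± 0.43), and the transcription factor TCF21 rose 14.9-fold from under 1 CPM in both WT libraries. The placental-type alkaline phosphatases ALPG and ALPP rose 14.4-fold and 11.5-fold. Their sequences are close enough that reads may be split between them, so the gene of origin is uncertain. Cyclin D1 (CCND1) rose 1.95-fold, from 612 and 482 CPM in WT to 1135 and 995 CPM in KO1. In KO2 CCND1 fell instead, to 401 and 361 CPM (log2 fold change −0.51), also past the edgeR threshold.

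In total 130 genes changed in KO1 at an adjusted p of 0.05 by edgeR with the set term, 86 higher and 44 lower, and 75 of them by more than 1 log2 unit. Besides those above, EPS8L3, SYT8, TRIM29 and PLEKHS1 rose most, by 8.28-fold, 5.78-fold, 5.25-fold and 5.00-fold. Apart from DPYSL5, the largest falls were in the zinc finger gene ZNF585B (12.6-fold), the desmosomal cadherin DSC3 (5.84-fold) and NAV3 (5.05-fold). LMAN1, a cargo receptor of the secretory pathway, fell 4.31-fold. TRMT2B fell 4.13-fold, SEMA3A, a secreted guidance cue, 3.86-fold, and the growth factor gene FGF9 3.74-fold. Log2 ratios in the HCT and HCT116 sets differed by over 1 for KRT13 (2.92 and 5.01) and ALPG (2.90 and 4.13). The same held for ALPP (2.45 and 3.92), EPS8L3 (2.13 and 3.67), SYT8 (1.54 and 3.02) and TRIM29 (1.67 and 3.08). It also held for DSC3 (−2.07 and −3.15) and SEMA3A (−2.37 and −1.07). The ratios of DPYSL5 (−6.24 and −8.27) differed too, but depend on the prior count, as KO1 had 0.402 and 0 CPM. Leaving out 1 library gave 215 genes without the HCT library of WT, 78 without the HCT116 library of WT, 86 and 69 without the HCT and HCT116 libraries of KO1, and 901 and 845 without those of KO2. The lone library of a group was then assumed to vary like the others.

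Direct targets of p53, the stress-activated transcription factor, were higher in KO1. Of 28 members tested, 27 had a positive log2 fold change, 3 rose and 0 fell at an adjusted p of 0.05 by edgeR, and adjusted over the list alone 10 rose and 0 fell. The 3 were the kinase gene PLK2 (2.32-fold, log2 fold change 1.21 ± 0.16, SE), the cell cycle inhibitor gene CDKN1A (1.89-fold, from 318 and 309 CPM to 517 and 687 CPM) and SESN1 (1.82-fold), a p53-induced repressor of mTORC1. The list's median log2 fold change was 0.40, with 0.24 in the HCT set and 0.51 in the HCT116 set. The camera test with a preset correlation gave an adjusted p of 4.65e-08 without the set term and 4.71e-08 with it. With an estimated correlation the adjusted p was 0.418 without the set term and 0.991 with it.

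Markers of differentiated intestinal epithelium were also past the threshold in KO1 by camera without the set term (adjusted p = 6.15e-05, and adjusted p = 0.418 with an estimated correlation) and not with the set term (adjusted p = 0.239). Only 6 of the 37 listed markers were expressed enough to test, and 1 of them rose and 0 fell by edgeR, while adjusted over the list alone 4 rose and 1 fell. The 1 was HNF4A, a transcription factor of the intestinal epithelium, 2.14-fold higher. Among other lists, FOSL2 (1.75-fold) and CCND1 of the 31 immediate early and MAPK genes rose and 0 fell, and adjusted over the list alone 7 rose and 2 fell. Of 33 genes of epithelial-mesenchymal transition and invasion, LAMB3 rose (1.79-fold) and vimentin (VIM) fell (2.38-fold), against 3 and 2 adjusted over the list alone. Of 17 Wnt target genes, CCND1 rose and RNF43, which encodes a ubiquitin ligase that limits Wnt receptors, fell 2.32-fold, against 2 and 1 adjusted over the list alone. TRIB3, an ATF4 target, fell 1.80-fold as the single change among 37 genes of that list, where 1 rose and 1 fell adjusted over the list alone.

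KO2 was compared with WT in the same way for the other guide. Interferon-stimulated genes were higher in KO2. Of the 34 list members tested, 21 rose and 0 fell at an adjusted p of 0.05 by edgeR with the set term, and 27 rose and 0 fell adjusted over the list alone. OAS1, an enzyme that senses double-stranded RNA, rose 17.9-fold from under 1 CPM, IFIT1, which binds viral RNA, 4.01-fold from 9.70 and 7.39 CPM to 42.6 and 26.7 CPM, and IFI6 2.96-fold. Their log2 fold changes were 4.16 ± 0.44, 2.00 ± 0.20 and 1.57 ± 0.16 (SE, n = 2 libraries per group). All 34 members had a positive fitted log2 fold change, with a median of 1.09, and median ratios within the sets of 1.14 (HCT) and 0.89 (HCT116). Camera gave an adjusted p of 2.89e-31 without the set term and 2.73e-20 with it, and with an estimated correlation the adjusted p was 0.202 and 0.821. Of 7 leukocyte markers tested beside them, 0 changed in KO2 by edgeR, also adjusted over the list alone (median log2 fold change −0.04).

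**Figure D1:**
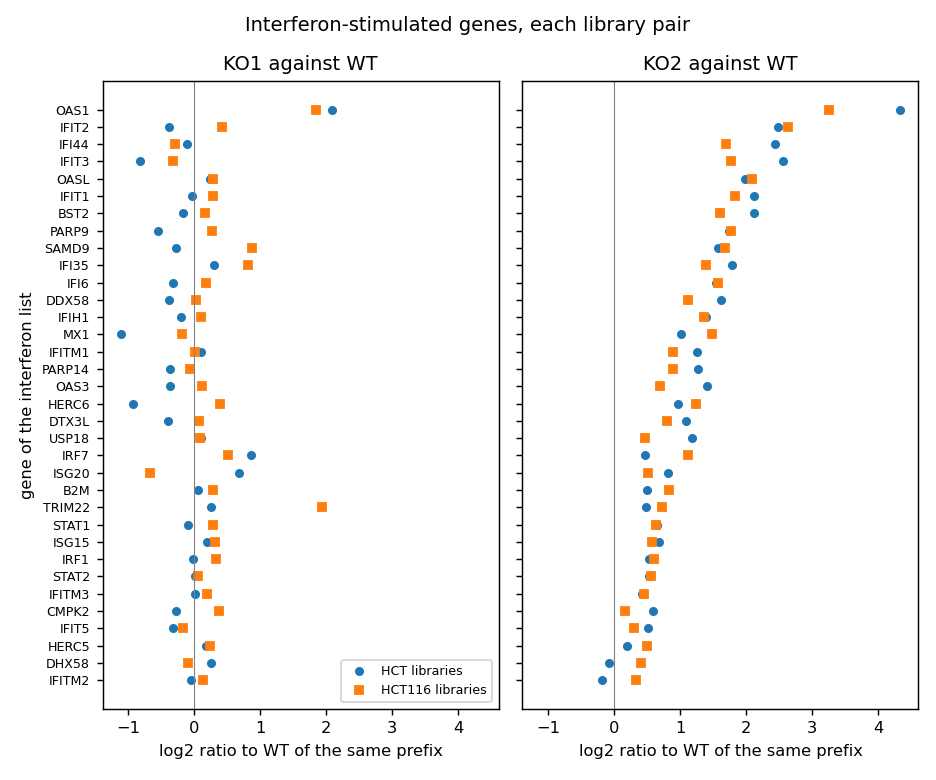
Log2 ratio to the WT library of the same name prefix for the 34 tested genes of the interferon list, with KO1 on the left and KO2 on the right. Each point is a single library pair, circles for the HCT set and squares for the HCT116 set, and most genes lie right of 0 in both sets of KO2, with a median of 1.14 in HCT and 0.89 in HCT116.

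Several genes were near or at 0 counts in KO2 in both sets. PRKAA2, a catalytic subunit of AMP-activated protein kinase, fell from 23.8 and 7.39 CPM in WT to 0.209 and 0 CPM (log2 fold change −7.00 ± 0.44, SE). It had 4 reads over both KO2 libraries against 460 in WT, so its SE understates counting error. MAP6, a microtubule-stabilising protein, had 1 read over both KO2 libraries against 314 in WT, a count ratio of 376 with a 95% exact counting interval of 66.9 to 14879. TUSC3 had 1 read against 107 (ratio 128, interval 22.5 to 5101) and LYL1 had 1 against 88 (ratio 105, interval 18.4 to 4203). The growth factor gene NRG1 had 0 reads in KO2 against 37 in WT, at least 14.7-fold lower, and TCF21 had 0 against 19, at least 7.57-fold lower, with a floor of 3 counts over the group. ICAM1, a cell adhesion protein, fell 18.1-fold and ZNF426 14.9-fold. Intervals and floors cover counting error only.

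The largest rise in KO2 was in DKK4, a secreted Wnt inhibitor that is itself a Wnt target, 62.0-fold from 0.195 and 0.0787 CPM, that is from 4 reads over both WT libraries to 314 in KO2. Keratin 5 (KRT5) rose 16.9-fold, RERG 14.4-fold, SEMA3A 9.88-fold and DHRS2 9.77-fold. APOBEC3G, a cytidine deaminase that restricts retroviruses, rose 13.2-fold and PARP10 10.1-fold. Log2 ratios in the HCT and HCT116 sets were 2.74 and 4.09 for SEMA3A, 3.14 and 4.40 for RERG and 4.34 and 3.26 for OAS1. Altogether 585 genes changed, 272 higher and 313 lower, and 236 of them by more than 1 log2 unit (edgeR, adjusted p of 0.05, set term). The count was 386 without the HCT library of WT, 317 without the HCT116 library of WT, 1658 without the HCT library of KO2 and 2170 without the HCT116 library of KO2.

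Transcripts of the mitochondrial genome were higher in KO2, where they made up 8.90% and 6.95% of counts in the HCT and HCT116 libraries, against 5.34% and 4.84% in WT. Of 13 genes, 5 rose and 0 fell by edgeR, and adjusted over the list alone 10 rose and 0 fell. MT-ND1 rose 1.78-fold, MT-CYB 1.65-fold and MT-ND6 1.51-fold. The camera adjusted p was 3.05e-06 without the set term and 1.79e-06 with it, and 0.202 and 0.821 with an estimated correlation.

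Genes of cholesterol and fatty acid synthesis were lower in KO2. Of 33 tested, 4 fell and 0 rose, and adjusted over the list alone 6 fell and 0 rose. INSIG1, a sterol-regulated anchor of the SREBP pathway, fell 1.95-fold (log2 ratios −1.46 in the HCT set and −0.46 in the HCT116 set) and MVD, an enzyme of the mevalonate pathway, 1.80-fold. Camera gave an adjusted p of 0.000358 without the set term and 0.00068 with it, and 0.202 and 0.821 with an estimated correlation. MVD lies in the chromosome 16 window described further on.

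Glycolysis and hypoxia genes were on balance lower in KO2 (median log2 fold change −0.31), with 3 of 34 lower and 1 higher by edgeR, and adjusted over the list alone 4 lower and 1 higher. HK2, the first enzyme of glycolysis, fell 1.71-fold and the lactate exporter SLC16A3 1.56-fold. CA9, a carbonic anhydrase induced by hypoxia, rose 4.26-fold, against the direction of the list. Genes of G2 and mitosis were lower as a list, with 1 of 35 log2 fold changes positive and a median of −0.24, but 0 members passed the edgeR test, and 0 adjusted over the list alone. Camera gave adjusted p of 0.0098 and 0.000357 for these 2 lists without the set term, and 0.00068 and 1.55e-05 with it. With an estimated correlation the adjusted p was 0.844 and 0.539 without the set term, and 0.899 and 0.821 with it. The median ratio of the glycolysis and hypoxia genes was −0.53 in the HCT set and −0.12 in the HCT116 set, and that of the G2 and mitosis genes −0.07 and −0.40. With the set term, camera's call for glycolysis and hypoxia ended without the HCT library of KO2 (adjusted p = 0.860), and that for G2 and mitosis without the HCT116 library of WT (0.123) or of KO2 (0.135). Without the set term the glycolysis and hypoxia call ended without the HCT library of WT (camera adjusted p = 0.994, with the direction turned) or the HCT116 library of KO2 (0.379), and the G2 and mitosis call without the HCT116 library of WT (0.391). Replication-dependent histone genes passed camera without the set term only (adjusted p = 0.0159, against 0.0709 with it, and adjusted p = 0.812 with an estimated correlation), and there it ended without the HCT library of WT (0.245) or the HCT116 library of KO2 (0.804). Of 10 tested, 1 rose (HIST1H2AC, 2.06-fold) and 0 fell, also adjusted over the list alone.

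Single members of other lists changed in KO2, while camera with the set term gave no call for those lists. In the endoplasmic reticulum stress list SEC24D (2.79-fold), DNAJB9 (1.73-fold) and HERPUD1 (1.45-fold) rose and 0 of 20 fell, with 4 and 0 adjusted over the list alone. Of 25 NRF2 targets, the transporters ABCC2 (2.22-fold) and ABCC3 (2.21-fold) and the oxidoreductase NQO1 (1.64-fold) rose and 0 fell, also adjusted over the list alone. HERPUD1 and NQO1 lie on chromosome 16, where the median log2 fold change in KO2 over 31 neighbouring genes was 0.14 around HERPUD1 and 0.23 around NQO1. Of 31 immediate early and MAPK genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone), among them KLF2 (2.06-fold), FOSL2 (1.85-fold) and FOSL1 (1.79-fold). Of 17 Wnt targets, 2 rose and 4 fell (2 and 6 adjusted over the list alone), with NOTUM 2.32-fold and RNF43 1.77-fold lower. THBS1 fell 3.64-fold and fibronectin (FN1) rose 1.97-fold in the invasion list, in which 2 of 33 rose and 2 fell, and 4 and 4 adjusted over the list alone. MUC1, another membrane mucin, rose 2.23-fold as the single change among 7 mucin genes tested, also adjusted over the list alone. The 21 genes tested near MUC3A on 7q22 gave no call as a list by camera with the set term (adjusted p = 0.729 in KO2 and 0.239 in KO1). Of 28 p53 targets 1 fell, PLK2 (1.62-fold), and 0 rose, also adjusted over the list alone, and camera gave no call for the list (adjusted p = 0.081 with the set term).

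Genes at the end of the long arm of chromosome 16 were lower together in KO2. Among 9584 autosomal genes with a mean log2 CPM of at least 3, set in GRCh38 order, the lowest median over 31 neighbouring genes in KO2 ran from ZC3H18 to DBNDD1, with 1 further gene after it on the chromosome. The median log2 fold change there was −0.66, a 1.58-fold fall, with 30 of 31 genes lower and 23 of them past the edgeR threshold. The median was −0.58 in the HCT set and −0.70 in the HCT116 set, and in KO1 it was −0.03 and −0.19. In 1000 shuffles of gene order, 0 gave a median as large in size, the largest being 0.32. The window holds MVD, RPL13, which fell 1.71-fold as the single change among 73 ribosomal protein genes (also adjusted over the list alone), and CDT1, which fell 1.54-fold as the single change among 36 replication genes (0 adjusted over the list alone). TCF25 (log2 fold change −1.29) and PIEZO1 (−1.22), named here after their values were seen, fell most in it. SLC7A5, an amino acid transporter of the ATF4 list that fell 1.84-fold in a list where 1 of 37 rose and 3 fell (2 and 3 adjusted over the list alone), lies shortly before the window. The median over the 31 genes centred on it was −0.46. Part of those genes belong to the window, so the value is not separate from it. Over the 31 genes just before the window, centred on KIAA0513, the median was −0.27 in KO2 and 0.01 in KO1. That KO2 value lay inside the largest shuffled size of 0.32, and the fit without the window keeps these genes.

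**Figure D2:**
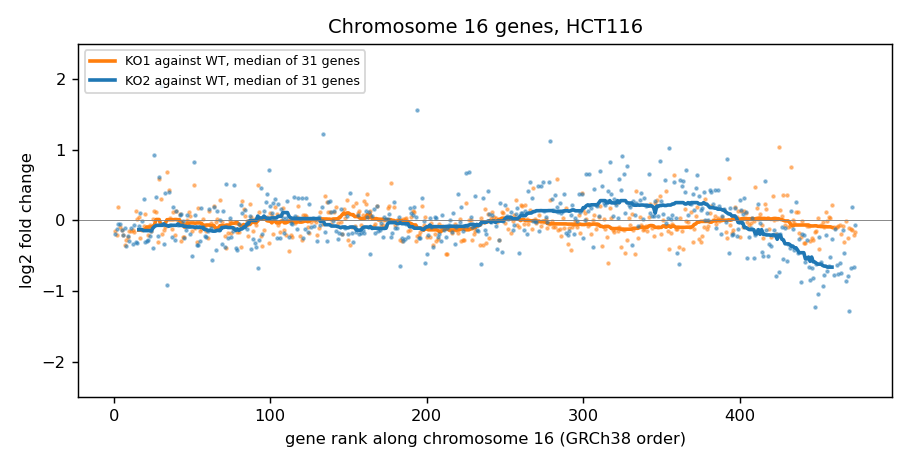
Log2 fold change against WT for 474 genes of chromosome 16 in GRCh38 order, points for single genes and lines for the median of 31 neighbouring genes, with KO1 and KO2 in separate colours. The KO2 line falls to −0.66 at the right end, the end of the long arm.

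The guides were compared directly by testing KO2 against KO1, in which WT cancels out. By edgeR with the set term 1220 genes differed, 537 higher and 683 lower in KO2, and 511 of them by more than 1 log2 unit. Higher in KO2 were DPYSL5 (log2 difference 7.19 ± 0.40, SE), RERG (6.65 ± 0.67), SEMA3A (5.25 ± 0.31), ZNF804A (4.57 ± 0.56) and DKK4 (4.40 ± 0.40). By counts RERG had 261 reads in KO2 and 2 in KO1, a ratio of 108 with a 95% exact interval of 29.7 to 899. For genes with few reads in a group, such as RERG, DPYSL5, ZNF804A and PRKAA2, the SE understates counting error. Lower in KO2 were PRKAA2 (−7.19 ± 0.44), TUSC3, MAP6, NRG1 and TCF21. For these the count ratios were 318 (interval 56.6 to 12614) in TUSC3 and 733 (131 to 28988) in MAP6, and KO2 was at least 63.5-fold lower in NRG1 and at least 112-fold lower in TCF21, which had 0 reads in KO2. The count was 391 and 729 without the HCT and HCT116 libraries of KO1, and 1921 and 3202 without those of KO2.

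The interferon list was higher in KO2 than in KO1, with 23 of 34 members higher and 0 lower by edgeR, 27 and 0 adjusted over the list alone, and a median difference of 1.09. Of the mitochondrial genes 6 of 13 were higher and 0 lower (9 and 0 adjusted over the list alone). Glycolysis and hypoxia genes were lower in KO2 than in KO1, with 8 of 34 lower and 1 higher (18 and 1 adjusted over the list alone). Of 35 G2 and mitosis genes 1 was lower, also adjusted over the list alone, and of 28 p53 targets 3 were lower (4 adjusted over the list alone), among them PLK2. With the set term, camera gave adjusted p of 1.76e-14, 2.16e-05, 2.16e-05, 0.000497 and 0.0404 for these 5 lists in that order. With an estimated correlation the adjusted p was 0.874 for each. Without the set term it gave 6.69e-21, 7.38e-05, 0.00312, 0.00679 and 0.0316 by camera, with an adjusted p of 0.426, 0.426, 0.827, 0.758 and 0.758 with an estimated correlation. With the set term camera's call for glycolysis and hypoxia ended without the HCT library of KO1 (adjusted p = 0.0744) or KO2 (0.0503), that for G2 and mitosis without the HCT116 library of KO2 (0.335), and that for p53 targets without the HCT116 library of KO1 (0.248) or the HCT library of KO2 (0.277). Without the set term the interferon and mitochondrial calls held without any 1 library, while glycolysis and hypoxia ended without the HCT library of KO1 (camera adjusted p = 0.869, with the direction turned) or the HCT116 library of KO2 (0.112), and G2 and mitosis without the HCT116 library of KO1 (0.178) or KO2 (0.074). The p53 call ended without either library of WT (camera adjusted p = 0.0546 and 0.0584), the HCT116 library of KO1 (0.311) or the HCT library of KO2 (0.348). Immediate early and intestinal lists passed camera without the set term (adjusted p = 0.0391 and 0.0112) and not with it (0.163 and 0.206). With an estimated correlation camera gave an adjusted p of 0.827 and 0.661 without the set term. There the immediate early call ended without the HCT library of KO1 or either library of KO2, and the intestinal call without either library of KO1. By edgeR with the set term 2 of 31 immediate early genes were higher and 8 lower (2 and 9 adjusted over the list alone), and 1 of 6 intestinal markers was lower (1 higher and 3 lower adjusted over the list alone).

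Few genes changed in the same direction with both guides. With the set term, 8 genes rose and 12 fell in both comparisons against WT, 20 in all. Those that rose with the smallest p were KRT13, TRIM29, RGS5, KRT15, SECTM1 and ADIRF. KRT13 rose 18.6-fold in KO1 and 4.19-fold in KO2, and ADIRF 1.66-fold and 2.07-fold. Those that fell were NAV3 (5.05-fold and 4.99-fold), ALPK2 (8.90-fold and 8.23-fold), RGS2 (2.58-fold and 3.55-fold), the EGF receptor ligand gene AREG (2.08-fold and 2.01-fold), RNF43 (2.32-fold and 1.77-fold) and EFNB2 (1.81-fold and 1.88-fold). Another 25 genes changed in opposite directions, 16 higher in KO1 and lower in KO2 and 9 the reverse. Among them were SEMA3A, DSC3, LMAN1, TCF21, PLK2, CCND1, LAMB3 and FOSL2.

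Both comparisons use the same WT libraries. In 20 simulations of unchanged groups against them, 0 genes were called in both comparisons. As no gene changed in them, few calls were likely, so that 0 does not tell how many observed calls come from the shared WT. Independent lists of these sizes would share 1.85 genes that rose, 1.09 that fell, 2.12 higher in KO1 and lower in KO2, and 0.944 the reverse. The correlation of log2 fold changes across genes was 0.0657, against 0.510 ± 0.0145 (SD) in the simulations, and their covariance was 0.0142, against 0.0379, a difference of −0.0237. The simulated correlation is that of noise alone, so it is no expectation for groups that changed. Genes are not independent replicates, and 2 WT libraries cannot be split into sets of 2, so part of the overlap may come from the shared controls. In log2 ratios that share no WT library, 9903 genes gave Pearson correlations across genes of 0.579 for KO1 and 0.482 for KO2 between the sets. Between KO1 in a set and KO2 in the other they were −0.000593 and −0.121. Spearman correlations were 0.387, 0.308, 0.0383 and −0.126 in the same order. The mean of both guides differed from WT in 81 genes, 39 higher and 42 lower, by edgeR with the set term. Leaving out a library moved the shared count of 20 to 37 without the HCT library and 8 without the HCT116 library of WT, 11 without the HCT library of KO1, and 175 and 136 without the HCT and HCT116 libraries of KO2.

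**Figure D3:**
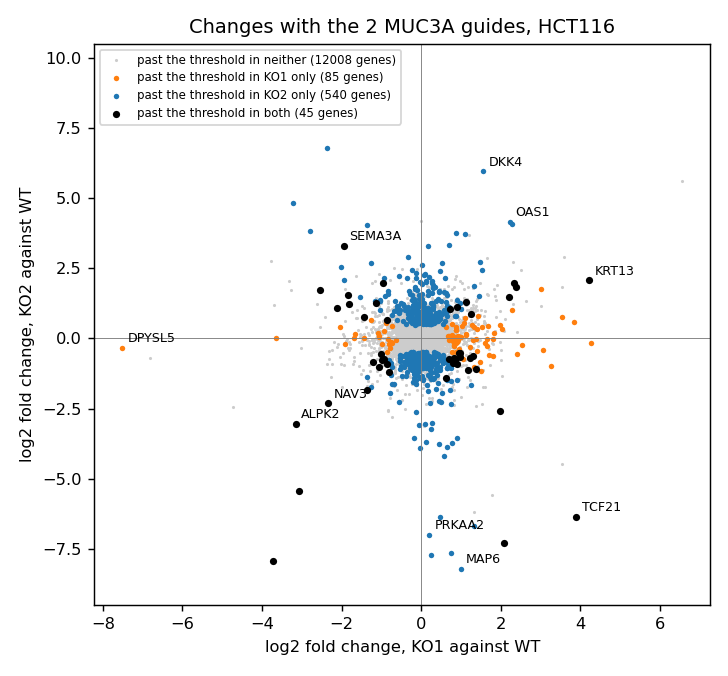
Log2 fold change of each of the 12678 tested genes in KO1 against WT (horizontal) and KO2 against WT (vertical) from the fit with the set term. Colours mark genes past an adjusted p of 0.05 in neither, either or both comparisons, and those past it in both comparisons are 20 genes with the same direction and 25 with opposite directions.

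The series title names the PI3K/Akt/mTOR pathway. Transcripts of its components did not shift as a list with either guide. Of 47 tested, 1 rose in KO1 (SESN1, 1.82-fold), while in KO2 1 rose (SESN3, 3.30-fold, a sestrin like SESN1) and 2 fell, PIK3R1, a regulatory subunit of PI3K (2.42-fold), and DDIT4, an mTORC1 inhibitor (1.86-fold). Within the HCT and HCT116 sets the log2 ratios were 0.95 and 2.72 for SESN3 and −1.45 and −0.36 for DDIT4. Adjusted over the list alone, 1 rose and 1 fell in KO1, and 2 rose and 4 fell in KO2. The median log2 fold change was −7.64e-06 in KO1 and −0.02 in KO2, and camera gave adjusted p of 0.957 and 0.517 without the set term and 0.957 and 0.384 with it. FOXO targets, which rise when Akt activity is low, did not pass as a list, with SESN1 the 1 of 21 that rose in KO1, SESN3 and BCL2L11 the 2 that rose in KO2, and 0 lower with either guide, also adjusted over the list alone. Phosphorylation was not analysed here.

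The authors' deposited tables list 15548 genes for KO1 and 15713 for KO2. An adjusted p under 0.05 in the authors' deposited table is given for 6 genes of KO1 (4 higher, 2 lower) and 30 of KO2 (12 higher, 18 lower). The authors' deposited filtered lists hold 97 genes for KO1 (67 higher, 30 lower) and 247 for KO2 (128 higher, 119 lower), each with an unadjusted p under 0.05 and an absolute log2 fold change over 1. By edgeR with the set term, 64 of the 94 KO1 genes tested here and 208 of the 231 KO2 genes passed, each in the same direction as in the authors' deposited table. By edgeR without the set term 0 of them passed. MUC3A has a log2 fold change of 0.06 in KO1 and −0.55 in KO2 in the authors' deposited table.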

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

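The tests of a GC and length trend were written before their results were seen. All other tests in this part, including that of the chromosome 16 window in separate sets, were chosen after the result was seen.

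The guides differed in 1220 genes when KO2 was tested against KO1 by edgeR with the set term, and 5 lists differed, with median log2 differences of 1.09 for interferon-stimulated genes, 0.62 for mitochondrial transcripts, −0.51 for glycolysis and hypoxia, −0.22 for G2 and mitosis and −0.18 for p53 targets. With an estimated correlation the adjusted p was 0.874 for each of the 5 lists, fry called 0 lists, and the calls for glycolysis and hypoxia, G2 and mitosis and p53 targets each ended without at least 1 library. The largest fitted log2 differences, KO2 minus KO1, were 7.19 for DPYSL5, 6.65 for RERG, 5.25 for SEMA3A, 4.57 for ZNF804A and 4.40 for DKK4, and −7.19 for PRKAA2, −7.99 for TUSC3, −9.20 for MAP6, −9.39 for NRG1 and −10.26 for TCF21. For genes with 0 to 3 reads in a group such fitted values depend on the prior count and bound nothing.

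Both guides came with virus and puromycin, and whether WT cells had them was not settled. A shared response to these cannot be told apart from one to MUC3A loss. A response to MUC3A loss shared by both guides would be a biological explanation for changes in both. It is argued against as the source of most of the changes by log2 ratios from separate sets, which share no library. Across genes their Pearson correlation was at most −0.000593 between the guides, against 0.579 and 0.482 for the same guide. The contrast was smaller by Spearman, with 0.0383 and −0.126 between the guides against 0.387 and 0.308 for the same guide. Guide matches in the transcripts of genes that fell are argued against too, since 0 called lower genes other than MUC3A hold a match with up to 3 mismatches, with introns and intergenic sites not searched. The labels do not say whether the libraries of a guide came from separately edited populations. Cell populations that differed before or apart from editing therefore cannot be told apart from the guides. The 10 genes with a mean log2 CPM of at least 1 that lie beyond 4 log2 units in KO2 against WT may be of this kind, as a hypothesis, and so may a response specific to a guide.

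The split of libraries by name prefix may partly reflect library preparation. GC content and gene length explained 39.9% of the variance of the set difference across genes, against 0.914% for KO1 and 0.416% for KO2, and the HCT116 set was higher in GC-rich genes (Spearman 0.554 across genes). They do not account for all of it, since 47.3% of tested genes still differed after the correction, against 63.9% before. A different cell line behind each prefix is argued against by 0 genes beyond 4 log2 units between the sets, among 11520 with a mean log2 CPM of at least 1, against 10 in KO2. Culture day, passage and sequencing run stay open, as no label names them, and the labels give no biological difference between the sets.

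The fall of genes at the end of chromosome 16 in KO2 is consistent with loss of a chromosome segment in those cells, a hypothesis found and tested on the same libraries. The lowest window found in either set was the same, and its median in the set not used to find it was −0.58 or lower. A GC and length trend is argued against: the window is GC-rich (median 60.8%, against 48.8% for all tested genes), and its median was −0.66 (95% bootstrap interval over genes −0.76 to −0.61) before and −0.65 (−0.74 to −0.61) after the correction. The intervals resample genes of a window chosen as the lowest, and cover neither that choice nor the spread between libraries. A shared regulatory change of the region stays open, since DNA copy number was not analysed here.

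Some genes appear in the table of a single guide, with 0 reads in WT, and enter no comparison above. BMP5, a secreted growth factor, had 112 and 67 reads in the HCT and HCT116 libraries of KO2, 179 in all. In KO2, AFF3 had 21 reads over both libraries, FGF14 14, IL13RA2 12 and AMHR2 11. In KO1, SLFN12 had 12 and PAMR1 11.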

How the results depend on the processing

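The name prefix as a block and everything combined with it were chosen after seeing the data, including the GC and length correction, the genes of either table and the fit without the chromosome 16 window. The alternatives without the block, filters included, were planned.

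Without the block, edgeR's counts were 0 in KO1, KO2, KO2 against KO1, the mean of both guides and the genes shared by both. They stayed 0 with other size factors, filters, limma-voom, 4 libraries, the log2 threshold of 1 and without any library. The replicate block gave 130, 585, 1220, 81 and 20, DESeq2 16, 42, 118, 15 and 1, and unadjusted p under 0.05 with a log2 fold change over 1 gave 143, 231, 409, 91 and 20. MUC3A's log2 fold change ran from −0.44 to 0.70 in KO1 and from −0.94 to 0.12 in KO2 without a library. The labels' replicate numbers were not run as a block, since columns carry none, and no pseudocount alternative applied to counts. The 4-library fit was not run for the mean of both guides, nor the GC correction for lists.

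With the block, the same 5 counts were 0 without it. The log2 threshold of 1 with adjusted p gave 75, 236, 511, 47 and 11, and with unadjusted p 264 in KO1, 728 between the guides, 169 in the mean and 42 shared. No filter gave 316 in KO1, 949 in KO2, 241 in the mean and 49 shared. DESeq2 gave 205 in KO1 and 152 in the mean. Using 4 libraries gave 879 in KO1 and 94 shared. Without a library the counts ran from 69 to 901, 317 to 2170, 391 to 3202, 39 to 1124 and 8 to 175, and the block then leaves a single residual degree of freedom. The GC and length correction, size factors, stricter filter, genes of either table and the fit without the chromosome 16 window kept all 5 counts within 1.5 times. With the block MUC3A's log2 fold change in KO1, 0.08, ran from −0.13 to 0.35 without a library, turning its sign without the HCT116 library of WT and, at −0.03, the HCT library of KO1, and in KO2 it ran from −0.77 to −0.08. Of 113 calls of named genes 0 were reversed, and 22 and 30 were lost without the HCT and HCT116 libraries of WT, 19 and 17 without those of KO1, 2 without the HCT library of KO2 and 113 without the block. The log2 threshold of 1 ended 38 with adjusted p and 38 with unadjusted p, and each other setting 0 to 4.

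Lists past the threshold without the block were 2, 6 and 7 (KO1, KO2, KO2 against KO1), and with it 1, 5 and 5. With an estimated correlation and with fry they were 0 in each. The block gave 1 in KO1, and 2 were called in KO1 with the stricter filter, with 4 libraries and without the block when the block was the starting fit. Leaving out a library gave 2 to 12 and 6 to 13 without the block, and 1 to 9, 6 to 13 and 4 to 8 with it. Interferon, mitochondrial and cholesterol lists in KO2 and p53 targets in KO1 kept their call in every setting but the estimated correlation and fry. The causes of these changes were not tested, apart from fewer libraries or genes where the setting says so. Depth limits genes near 3 counts.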

Other observations

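The analyses of neighbouring genes were chosen after seeing the data. Genes that neighbour each other changed together more often than shuffled gene order gave. In KO2 45 pairs of neighbouring genes were called in the same direction, against a mean of 12.2 and a maximum of 24 in 1000 shuffles, among 480 called genes. The lowered chromosome 16 window held 16 of these 45 pairs. Without its genes 29 pairs remained, against a mean of 10.9 and a maximum of 23, and without chromosome 16 there were 27, against a mean of 10.3 and a maximum of 26. In KO1 10 pairs were, against a mean of 0.61 and a maximum of 4, among 105 called genes. The highest window in KO2 lay on the same chromosome as the lowest, from CSNK2A2 to ZDHHC1, with a median log2 fold change of 0.28, 28 of 31 genes higher and 5 of them past the threshold, and 6 of 1000 shuffles as large. The highest window in KO1 ran from NUDT18 to PTK2B on chromosome 8, with a median of 0.23, 24 of 31 genes higher and 3 of 1000 shuffles as large.

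Remaining lists showed few calls by edgeR with the set term. Of 39 nuclear-encoded oxidative phosphorylation genes and 31 MYC and ribosome biogenesis genes, 0 changed with either guide, also adjusted over the list alone. Of 34 apoptosis regulators 0 changed in KO1, while in KO2 BCL2L11 rose 1.69-fold and BCL2L1, an inhibitor of apoptosis, fell 1.82-fold (2 rose and 1 fell adjusted over the list alone). Of 32 autophagy and lysosome genes 0 changed in KO1 and 2 rose in KO2, GABARAPL1 (1.73-fold) and ATP6V0D1 (1.71-fold), also adjusted over the list alone. ATP6V0D1 lies on chromosome 16, where the median log2 fold change in KO2 over 31 neighbouring genes was 0.25. Of 15 NF-kB targets 0 changed in KO1 (1 rose adjusted over the list alone), while in KO2 LIF rose 1.46-fold and ICAM1 fell (2 and 1 adjusted over the list alone). CA2 fell 1.85-fold in KO2 among the 6 intestinal markers (1 rose and 2 fell adjusted over the list alone), and EPRS, a tRNA synthetase of the ATF4 list, fell 1.74-fold.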
